A study of Mus musculus with 2 samples.

How the data were processed

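Long-read RNA-seq was done on total RNA of hippocampus tissue from B6NCrl mice in 2 samples, on the PacBio platform by the title of the protocol that the labels cite. The samples form 1 group, and the replicate numbers come from the labels. The deposited values are raw counts of long reads per transcript model in each library, given by the authors without normalization. Per the file headers and the library descriptions deposited with them, the counts were made from alignments to the mouse genome mm10 with the GENCODE M21 annotation and spike-in sequences. TALON is named as the source of the transcript models in the deposited annotation files, which give the exon coordinates on mm10. The aligner, the read filters and all versions are not given in the sources used here. Each model carries a class, Known, ISM, NIC, NNC, Genomic, Antisense or Intergenic, as the authors' files give it. Every Known model (25684 in replicate 1 and 22771 in replicate 2) had exons identical to those of the GENCODE M21 annotation used here for coding segments, transcript lengths and GC content.

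Classes are assigned per library, and a read that stops early can only be assigned to the part of the chain that it covers, so shares of ISM and of the full-length classes depend on read completeness. Of the models with reads, 63.8% in replicate 1 and 63.0% in replicate 2 had 1 read. The mean model length over reads was 2687 and 2681 nt.

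Counts were summed per gene, and CPM was computed here over all reads in mouse genes, 1999531 and 1781979, leaving spike-ins out. Log2 ratios are log2 of (CPM + 0.5) in replicate 2 over replicate 1. With 1 group no test between conditions exists and edgeR's quasi-likelihood test has no groups to compare. Genes with at least 10 reads over both libraries were tested with an exact two-sided binomial test of the reads in replicate 1 against its share of all gene reads, with Benjamini-Hochberg adjustment and a threshold of 0.05. Transcripts of the classes Known, NIC and NNC were taken as full-length models. The leading transcript was compared with the next by an exact two-sided binomial test, and its share between libraries by Fisher's exact test in genes with at least 20 full-length reads in each library. Inclusion of a cassette exon is the reads that hold it as an internal exon over these plus the reads whose intron spans it, for exons with at least 20 informative reads in each library and 5% to 95% inclusion; ISM reads count where they cover it. Splice chains were matched between libraries by chromosome, strand and introns. Wilson 95% intervals were used for shares and exact Clopper-Pearson 95% intervals for ratios of named genes with reads in both libraries. Folds against 0 reads used a floor of 3 reads per library. Such a fold, given as at least a value, takes the count of the other library as it is. It allows neither for counting error there nor for the choice of the largest ratios.

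The tests, the alternatives of the first set, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes the 20 genes with the highest mean CPM; the 4 most abundant genes of each list; the 10 genes with the largest ratio in each direction among those that differed; among 60 isoform genes fixed by name, the 12 with the most reads for the leading transcript and the 20 cassette exons with the most informative reads; the 10 genes with the most reads led by a NIC or NNC transcript in both libraries; and sex-linked genes. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen. The 26 lists cover excitatory neurons, CA1, CA2 and CA3 pyramidal cells, dentate granule cells, interneurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, meningeal fibroblasts, choroid plexus, ependymal cells, blood, thalamus, cortical layers, striatum, immediate early genes, synaptic vesicle and postsynaptic genes, Alzheimer-associated genes, heat shock and glucocorticoid response, ribosomal proteins and mitochondrially encoded genes. A list's log2 ratio of median CPM was placed among 10000 random lists of equal size matched on mean expression, drawn from the 50 genes on each side.

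Alternatives fixed in advance were TMM and DESeq2 scaling, other read minimums, known transcripts only, ISM transcripts included, mitochondrial genes left out, other thresholds for a second transcript and each replicate left out. Added after seeing the data were 6 more: splines with 6 degrees of freedom of the ratio on transcript length or GC content, fitted on genes with at least 100 reads, for the gene test, the length spline for the lists, a 2-fold limit, and a common class for splice chains in the isoform test and the leading transcripts. The gene test, the isoform test, the length spline and the list ratio were tested on simulated data; the GC spline and the tests of leading transcripts and cassette exons were not. The simulated reads had Poisson counting noise only, without further spread between libraries, so the calls among unchanged genes do not describe the real libraries. For the gene test, 41 of 97 genes changed 2-fold, 82 of 98 changed 4-fold and 4 of 12630 unchanged genes were called. For the isoform test, 101 of 196 genes changed 4-fold and 5 of 6140 unchanged genes were called. A simulated length trend gave 400 calls without the spline and 10 with it, over 12690 genes, and a list of 16 genes raised 2-fold over 20041 genes gave a log2 ratio of 1.03.

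Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, patsy 1.0.2 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for TMM factors and the coefficient of variation and DESeq2 1.42.0 for size factors. Spike-in reads were left out of all comparisons.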

Results

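The series holds 2 long-read RNA-seq libraries of mouse hippocampus tissue from the inbred strain B6NCrl. Both belong to 1 group, labelled as control, and carry the biological replicate numbers 1 and 2. In long-read RNA-seq a read can span a whole cDNA, so each read was assigned to a transcript model and not only to a gene. With 1 group there was no comparison between conditions, and the data address which genes and transcripts control hippocampus contains and how far the 2 libraries differ. Replicate 1 had 1999531 reads in mouse genes and replicate 2 had 1781979. Annotated genes with at least 1 read numbered 18736 and 17267, and 15931 of the 20072 genes seen in either library were seen in both. Protein-coding genes took 95.1% and 96.4% of the reads, and mitochondrial genes 0.0481% and 0.0228%. A count of 0 allows up to 3 reads, which is 1.5 counts per 1000000 gene reads (CPM) in replicate 1 and 1.68 CPM in replicate 2. Both samples carry the same donor identifier and nothing in the labels says that they came from separate animals, so differences between them may be technical. Each test on reads compares the 2 libraries, not conditions, and its p-value sets their difference against counting error alone, without any spread between samples. The intervals cover counting error only too. The floors cover that of the count of 0 alone, so a fold given as at least a value is not a lower 95% limit.

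A label describes both samples as female, while the field for sex was left uncollected. Xist, the RNA that silences an X chromosome in female cells, had 40 reads (20.0 CPM) in replicate 1 and 22 reads (12.3 CPM) in replicate 2. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 reads in each library.

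Hspa8 (ENSMUSG00000015656.17, chromosome 9, 40800984 to 40810087, mm10), a constitutive heat shock chaperone, was the most abundant gene at 13748 ± 18.7 CPM (SD, n = 2). Ckb, the brain creatine kinase, followed at 7210 ± 616 CPM, and Mbp (ENSMUSG00000041607.17, chromosome 18, 82475146 to 82585637), which encodes myelin basic protein, at 6403 ± 656 CPM. Next came the actin gene Actg1 at 5276 ± 1309 CPM, the translation elongation factor gene Eef2 at 5185 ± 356 CPM and Apoe (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188), the lipid carrier made mainly by astrocytes, at 4955 ± 2083 CPM. The rest of the 20 most abundant genes were Pkm, Ndrg4, Fth1, Tuba1a, Eef1a1, Tubb2a, Snap25, Atp5a1, Aldoa, Sparcl1, Cpe, Eif4a2, Chn1 and Trf, from 4327 ± 462 CPM for Pkm down to 2777 ± 526 CPM for Trf. These 20 genes took 9.15% of the reads of replicate 1 and 9.36% of those of replicate 2. Reads of actin, tubulin, elongation factor, globin and ribosomal protein genes are uncertain, because these families have near-identical copies and the rule for reads that match several copies is not given in the sources used here.

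Neuronal gene lists were present throughout. Chn1, a Rac-regulating chimaerin, reached 2794 ± 970 CPM, Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase, 849 ± 597 CPM, Baiap2 767 ± 335 CPM and the transcription factor gene Neurod6 160 ± 47.8 CPM. Of the 10 excitatory neuron genes, 5 were higher in replicate 2 and 0 in replicate 1, also 5 adjusted over the list alone, and the list summed to 4873 ± 1957 CPM. Among CA1 pyramidal cell genes, Wfs1 was at 299 ± 87.1 CPM, Mpped1 at 293 ± 63.5 CPM and Fibcd1 at 93.4 ± 20.3 CPM, all 3 higher in replicate 2, while Ccn3 was at 18.2 ± 1.14 CPM. CA2 genes summed to 272 ± 34.7 CPM, with Ptpn5 at 162 ± 20.1 CPM; 2 of the 7 tested, Pcp4 and Amigo2, were higher in replicate 1, also 2 adjusted over the list alone. CA3 genes summed to 422 ± 45.7 CPM, led by Bok at 155 ± 6.25 CPM, and Nnat was higher in replicate 1 (log2 ratio of replicate 2 over replicate 1 -1.36, adjusted p 2.0e-10, exact binomial test); 2 of 10 differed, also 2 adjusted over the list alone. Dentate granule cell genes summed to 1097 ± 224 CPM, with the calcium-binding protein gene Calb1 at 404 ± 36.6 CPM and C1ql2 at 287 ± 133 CPM. Of 15 tested, 3 were higher in replicate 2, among them C1ql2 (0.98) and Bcl11b (0.79), and 2 in replicate 1; 6 passed when adjusted over the list alone. With known transcripts only, 1 of 11 dentate granule cell genes differed, higher in replicate 2. Interneuron genes summed to 1416 ± 96.8 CPM. Gad1, which encodes a GABA-synthesising enzyme, was at 642 ± 22.9 CPM, and of 14 tested 1 was higher in replicate 1, also 1 adjusted over the list alone.

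Synaptic genes were among the most abundant of the fixed lists. The 16 synaptic vesicle and release genes summed to 11048 ± 634 CPM, led by Snap25, a SNARE protein gene, at 3537 ± 785 CPM and the vesicle protein gene Syp at 1454 ± 327 CPM. Of these, 6 were higher in replicate 2, including Snap25 (0.46), Cplx1 (0.40) and Nsf (0.23), and 7 in replicate 1, including Syp (-0.46); 13 passed when adjusted over the list alone. The 16 postsynaptic and glutamate receptor genes summed to 5243 ± 823 CPM, with the AMPA receptor genes Gria1 at 1121 ± 68.4 CPM and Gria2 at 1040 ± 130 CPM. Of 15 tested, 5 were higher in replicate 2 and 0 in replicate 1, and 6 passed when adjusted over the list alone. Immediate early genes, which neurons switch on after activity, summed to 1101 ± 470 CPM. Of 13 tested, 5 were higher in replicate 2 and 0 in replicate 1, and 6 passed when adjusted over the list alone. Junb had a log2 ratio of 1.23 (adjusted p 5.7e-52, exact binomial test), Nr4a1 of 1.5, Dusp1 of 1.33 and Arc of 0.59.

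Glial genes were abundant. The 15 astrocyte genes summed to 14725 ± 1187 CPM, with Sparcl1 at 3076 ± 670 CPM, the aldolase gene Aldoc at 2283 ± 157 CPM and the glutamate transporter gene Slc1a3 at 847 ± 13.0 CPM. Of these 15, 6 were higher in replicate 2 and 2 in replicate 1, Apoe among the latter (-0.88), also 8 in all adjusted over the list alone. The 15 oligodendrocyte genes summed to 14778 ± 2003 CPM, with the transferrin gene Trf and the myelin gene Cnp at 1390 ± 239 CPM. Mbp, Trf and Cnp were among the 5 higher in replicate 2, 4 were higher in replicate 1, and 11 passed when adjusted over the list alone. Oligodendrocyte precursor genes summed to 301 ± 2.80 CPM; Olig1 was higher in replicate 2 (0.62), Olig2 (-2.78) and Tnr (-1.01) in replicate 1, and 4 of the 9 tested passed when adjusted over the list alone. Microglia genes summed to 2217 ± 382 CPM. The protease inhibitor gene Cst3 (1174 ± 396 CPM) was higher in replicate 1 (-0.70), while the purinergic receptor gene P2ry12 was higher in replicate 2 (0.47); 5 of 13 were higher in replicate 1, 2 in replicate 2, and 8 passed when adjusted over the list alone.

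Vascular, barrier and neighbouring-tissue genes followed. Endothelial genes summed to 1613 ± 377 CPM, and 5 of 11 were higher in replicate 1, including Bsg (-0.63) and the tight junction gene Cldn5 (-0.56), against 0 in replicate 2; 7 passed when adjusted over the list alone. Mural cell genes summed to 284 ± 1.38 CPM, with 1 of 7, Vtn, higher in replicate 2 and 0 adjusted over the list alone. Meningeal fibroblast genes summed to 404 CPM in replicate 1 and 58.9 CPM in replicate 2, and 4 of 6 were higher in replicate 1, including the collagen gene Col1a1 and the proteoglycan gene Dcn (-1.67), also 4 adjusted over the list alone. Choroid plexus genes summed to 471 ± 93.7 CPM, and 4 of 6 were higher in replicate 1, also 4 adjusted over the list alone. Ttr, which encodes transthyretin, had 114 and 8 reads and Enpp2 905 and 696. Enpp2 made up most of the sum, 453 of 538 CPM in replicate 1 and 391 of 405 CPM in replicate 2. The sum therefore says little about the other genes of this list. Ecrg4 of this list was not matched by that symbol. Ependymal genes summed to 7.75 ± 4.61 CPM and blood genes to 61.3 ± 21.6 CPM. Of 2 ependymal genes tested 0 differed, also 0 adjusted over the list alone, and of 5 blood genes the haemoglobin genes Hba-a1 and Hba-a2 were higher in replicate 1, also 2 adjusted over the list alone. Thalamus genes summed to 172 ± 35 CPM, cortical layer genes to 178 ± 13.9 CPM and striatum genes to 180 ± 19.4 CPM. Prkcd of the thalamus list was higher in replicate 2 (0.95), 1 striatum gene was higher in replicate 1, and 0 of 7 cortical layer genes differed; adjusted over the list alone the counts were 1, 1 and 0.

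The 20 Alzheimer-associated genes summed to 8813 ± 2206 CPM, led by Apoe and by App, the amyloid precursor gene, at 1287 ± 342 CPM. App (-0.55) and Apoe were higher in replicate 1, Bin1 (0.33) and Clu (0.16) in replicate 2, 4 genes each way, and 9 passed when adjusted over the list alone. With TMM or DESeq2 scaling the split was 2 higher in replicate 1 and 6 in replicate 2. Heat shock and glucocorticoid response genes summed to 14956 ± 70.9 CPM, most of it Hspa8; 2 of 8 were higher in replicate 2, including the kinase gene Sgk1 (1.02), and 0 in replicate 1, also 2 adjusted over the list alone. Of 83 ribosomal protein genes tested, 54 were higher in replicate 1, 2 in replicate 2 and 27 did not differ; 61 passed when adjusted over the list alone. With the trend of the ratio on transcript length removed, an alternative chosen after the data were seen, 19 differed, 17 of them higher in replicate 1. Rpl3 (-0.68), Rpl4 (-0.42), Rplp0 (-1.07) and Rps3a1 (-1.05) were the most abundant. Mitochondrially encoded genes summed to 481 CPM in replicate 1 and 228 CPM in replicate 2, with 4 of 11 higher in replicate 1, led by mt-Co1 (-2.44), and 6 adjusted over the list alone.

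Set against 10000 random lists matched on expression, 4 of the 26 lists had a log2 ratio of medians outside the 2.5 to 97.5 percentile range, all on the side of replicate 1. These were meningeal fibroblasts (-2.21, percentile 0.01), ribosomal proteins (-0.58, below all random lists), microglia (-0.73, percentile 1.30) and CA1 pyramidal cells (-1.04, percentile 2.04). The CA1 value differs in sign from the median over the ratios of its tested genes, 0.14, and from its calls, 3 higher in replicate 2 and 1 in replicate 1, also 4 adjusted over the list alone. With the trend of the ratio on transcript length removed, the ribosomal protein value was -0.07 (percentile 27.4), the microglia percentile 3.69 and the CA1 percentile 4.64, an alternative chosen after the data were seen. With known transcripts only, the percentiles were 3.28 for meningeal fibroblasts, 10.7 for microglia and 30.6 for CA1. These percentiles describe the 2 libraries only.

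Some of these calls ended under other settings. Of 59 genes that differed among the 4 most abundant of each list, 53 also differed with TMM scaling, 51 with known transcripts only and 52 with the length trend removed, and 0 turned (adjusted p of the exact binomial test throughout). With the length trend removed the call ended for Hba-a1 (log2 ratio -0.82 before and -0.22 after, adjusted p 0.757), Hba-a2 (-1.10 and -0.48, 0.477), Pcp4 (-1.08 and -0.48, 0.379), mt-Nd2 (-1.18 and -0.72, 0.147), Tnr (-1.01 and -0.77, 0.116), mt-Cytb (-1.16 and -0.76, 0.105) and Bin1 (0.33 and 0.17, 0.0883). With TMM, which shifted each ratio by 0.14, it ended for Aldoc (adjusted p 0.981), Enpp2 (0.586), Hba-a1 (0.115), Hba-a2 (0.0704), the prolactin receptor gene Prlr of the choroid plexus list (0.0661) and Tnr (0.0613). With known transcripts only, the log2 ratio of Amigo2, taken here without the added 0.5, went from -1.30 over 48 and 17 reads to -0.43 over 15 and 10 (adjusted p 0.741). That of Bcl11b went from 0.80 over 155 and 240 reads to 0.77 over 25 and 39 (0.128). The call also ended for Clu (0.16 and 0.10, adjusted p 0.310), Fibcd1 (0.45 and 0.40, 0.215), P2ry12 (0.47 and 0.36, 0.147), Gria1 (0.12 and 0.11, 0.125), Prlr (-1.87 and -1.81, 0.0783) and Vtn (0.44 and 0.41, 0.0769). With a minimum of 1 read it ended for Hba-a1, Vtn, Prlr, P2ry12 and Clu (0.0557 to 0.0757), whose ratios that setting leaves as they were. Scaling by TMM also moved the number of calls in the blood list from 2 to 0, in choroid plexus from 4 to 2, in endothelial cells from 5 to 3, in thalamus from 1 to 2, in immediate early genes from 5 to 8 and in heat shock and glucocorticoid response genes from 2 to 4. The calls higher in replicates 1 and 2 were then 1 and 4 for dentate granule cells, 1 and 2 for interneurons, 7 and 9 for synaptic vesicle genes, 1 and 8 for astrocytes and 1 and 1 for oligodendrocyte precursors. With the length trend removed they were 2 and 3 for microglia, 1 and 2 for interneurons and for CA3 cells, 1 and 3 for dentate granule cells, 5 and 7 for synaptic vesicle genes, 1 and 1 for oligodendrocyte precursors, 2 and 1 for heat shock and glucocorticoid response genes, 3 and 0 for endothelial cells, 2 and 0 for mitochondrial and for striatum genes, 1 and 0 for cortical layers and 0 and 0 for blood. With known transcripts only they were 1 and 5 for excitatory neurons, 0 and 2 for CA1, 1 and 0 for CA2 and CA3, 2 and 0 for interneurons, 1 and 3 for postsynaptic genes, 5 and 1 for microglia, 0 and 2 for thalamus, 1 and 0 for cortical layers and 0 and 0 for mural cells and striatum.

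**Figure D1:**
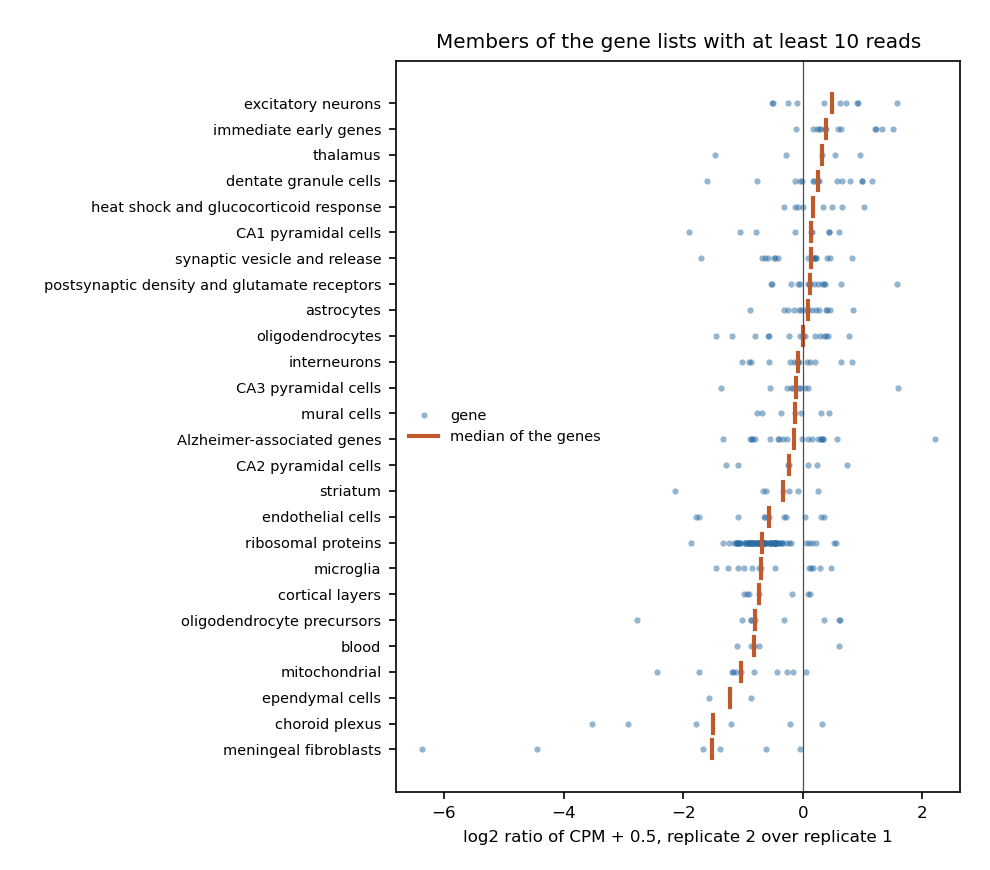
Each point is a gene of a fixed list with at least 10 reads over both libraries; the horizontal axis is the log2 ratio of CPM + 0.5 in replicate 2 over replicate 1, and the bar is the median over the list's genes. The excitatory neuron median lies at 0.48, the ribosomal protein median at -0.68 and the meningeal fibroblast median at -1.53.

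Among the 10 genes with the largest ratios on the side of replicate 1 were Pmch, Hcrt, Avp, Slc6a3, Th and Col1a1. Pmch (ENSMUSG00000035383.7, chromosome 10, 88091072 to 88092375), the precursor of melanin-concentrating hormone, had 178 reads in replicate 1 and 0 in replicate 2, at least 52.9-fold higher. Hcrt (ENSMUSG00000045471.4, chromosome 11, 100761069 to 100762931), the orexin precursor, had 125 and 0 reads (at least 37.1-fold higher), and Slc6a3 (ENSMUSG00000021609.6, chromosome 13, 73536747 to 73578672), the dopamine transporter gene, 140 and 0 reads (at least 41.6-fold higher). Th (ENSMUSG00000000214.11, chromosome 7, 142892752 to 142931128), the rate-limiting enzyme of catecholamine synthesis, had 228 and 5 reads (40.6-fold higher, exact 95% interval 17.2 to 126). The vasopressin gene Avp had 47 and 0 reads, at least 14.0-fold higher. Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042), a fibrillar collagen gene, had 547 and 5 reads, 97.5-fold higher (interval 41.5 to 301). Arhgap36 (69 and 0 reads, at least 20.5-fold higher), Slc10a4 (38 and 0 reads, at least 11.3-fold higher), the lincRNA A230006K03Rik (136 and 3 reads, 40.4-fold, interval 13.5 to 198) and Klhl10 (99 and 1 reads, 88.2-fold, interval 15.5 to 3520) completed the 10 largest ratios on this side. Klhl10 is uncertain, because an unannotated locus on the same strand over it held 0 reads in replicate 1 and 72 in replicate 2. No read of Klhl10 or of A230006K03Rik was of the class Known, so A230006K03Rik is uncertain too.

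On the other side, Cotl1 (ENSMUSG00000031827.13, chromosome 8, 119809222 to 119840544), a gene for an actin-binding protein, had 16 reads in replicate 1 and 194 in replicate 2, 13.6-fold higher (interval 8.17 to 24.3). Max (ENSMUSG00000059436.13, chromosome 12, 76937269 to 76962201), the dimerisation partner of Myc, had 13 and 123 reads, 10.6-fold higher (5.98 to 20.5), and the lincRNA B230209E15Rik 13 and 113 reads, 9.75-fold higher (5.48 to 18.9). The others had few reads. 3110053B16Rik had 1 and 18 reads (20.2-fold, interval 3.19 to 842) and 1110017D15Rik 1 and 16 (18.0-fold, 2.79 to 753). Pcdha1 had 0 and 20 reads (at least 7.48-fold higher), Gm45894 0 and 19 (at least 7.11-fold), Gm37676 and Gm11343 each 0 and 14 (at least 5.24-fold) and 4930562C15Rik 0 and 13 (at least 4.86-fold). Pcdha1 lies in a cluster of genes with shared exons, Gm11343 is a processed pseudogene, and unannotated loci on the same strand overlapped Gm37676 and Gm45894, so these 4 are uncertain. 4930562C15Rik is uncertain too, since it, like Pcdha1, Gm11343 and Gm45894, had no read of the class Known. B230209E15Rik lies on the same strand of chromosome 7 (61529871 to 61615327) as A230006K03Rik (61127996 to 61311721), which went the other way. Whether reads were assigned to another gene in 1 of the libraries was not tested.

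In all, 2872 of the 12864 genes with at least 10 reads differed at an adjusted p under 0.05 (exact two-sided binomial test with Benjamini-Hochberg adjustment), 1738 higher in replicate 1 and 1134 in replicate 2. The median log2 ratio of the tested genes was -0.15; scaling by TMM or by DESeq2 size factors shifted all ratios by 0.14 and turned the split, from 39.5% of calls higher in replicate 2 to 59.3% and 59.1%. With the length or GC trend removed it was 50.7% and 50.3%. Each spline also shifts the centre of the ratios, as scaling does, so this move of the split does not single out either trend. The common biological coefficient of variation from edgeR was 24.8%, and 935 calls reached at least 2-fold, 158 of them higher in replicate 2, a limit chosen after the data were seen. Across 5802 genes with at least 100 reads the log2 CPM values had a Pearson r of 0.914 and a Spearman rho of 0.889; these are correlations across genes, which are not independent replicates. Among these genes the median ratio moved with transcript length, from -0.51 in 261 genes under 1000 nt to 0.19 in 1631 genes of 2000 to 3000 nt and -0.18 in 1324 genes over 4000 nt.

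**Figure D2:**
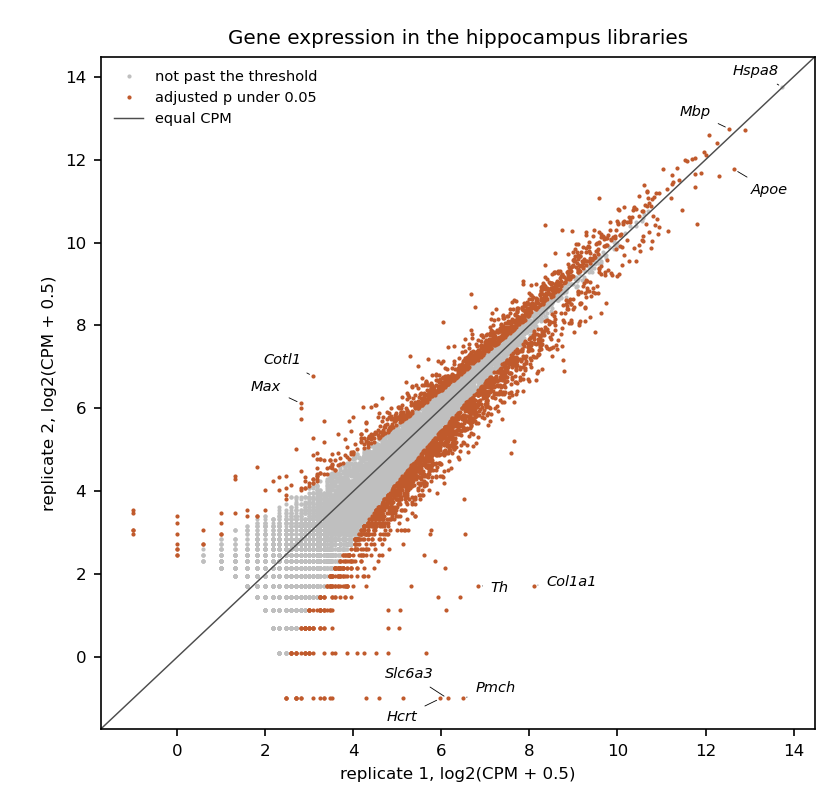
Each point is a gene with at least 10 reads over both libraries, placed by its log2(CPM + 0.5) in replicate 1 (horizontal axis) and replicate 2 (vertical axis); coloured points are the 2872 genes past the adjusted p threshold and the line marks equal CPM. Pmch, Hcrt and Slc6a3 lie on the row of genes with 0 reads in replicate 2.

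Most reads followed annotated transcripts. Reads of the class Known, whose transcript is annotated, made up 73.5% ± 1.12 (SD, n = 2) of gene reads, 72.7% (Wilson 95% interval 72.7 to 72.8) in replicate 1 and 74.3% (74.2 to 74.4) in replicate 2. Incomplete splice matches (ISM), which carry part of an annotated chain, took 9.83% ± 0.014. Transcripts that combine annotated splice sites in an unannotated way (NIC) took 6.73% ± 0.049, and those with an unannotated splice site (NNC) 4.00% ± 0.073. Reads of the class Genomic took 3.36% ± 0.445, those antisense to a gene 2.25% ± 0.502 and intergenic reads 0.310% ± 0.069. The Known share was larger in replicate 2 (Fisher's exact test p 5.7e-268), the Genomic (p 1.7e-252) and Intergenic (p 1.0e-65) shares in replicate 1, and the ISM shares did not differ detectably (p 0.517). By the same test the NIC (6.76% and 6.70%, p 0.0077) and NNC (4.05% and 3.94%, p 3.6e-07) shares were larger in replicate 1 by little. Over transcripts with at least 2 reads, the ISM share was 8.59% in replicate 1 and 8.72% in replicate 2, which differed (Fisher's exact test p 1.4e-05). The NIC share was then larger in replicate 2 (5.76% and 5.84%, Fisher's exact test p 0.0021). The Antisense share was 2.61% (2.59 to 2.63) in replicate 1 and 1.90% (1.88 to 1.92) in replicate 2.

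In most of the fixed isoform genes, a single transcript led in both libraries. Mbp-211 took 78.6% ± 2.57 (SD, n = 2) of the full-length reads of Mbp, Apoe-206 97.1% ± 0.606 of Apoe, and Pkm-202 89.3% ± 0.188 of the pyruvate kinase gene Pkm. Ndrg4-202 took 77.9% ± 3.09, Snap25-201 90.2% ± 1.47, App-201 91.9% ± 0.676 and Cnp-201 71.7% ± 0.415. Ndrg2-202 led with 45.8% ± 0.406, ahead of Ndrg2-201, and Camk2b-209 with 69.8% ± 5.14. Apbb1, which encodes an adaptor protein that binds the amyloid precursor protein, was led by an unannotated NIC transcript of 14 exons (chromosome 7, 105558483 to 105581192, minus strand) with 62.3% ± 1.71. Of 54 isoform genes with at least 20 full-length reads in each library, the leading transcript exceeded the next in 49 at an adjusted p under 0.05 (exact two-sided binomial test on summed reads). Mef2c, Nnat, Add1, Cadm1 and Stx3 were the exceptions. A lead in summed reads need not hold in each library. As named, the leader of Atp2b1 had 0 of 130 reads in replicate 2, and that of Map2 had 38 there against 48 for the next. In replicate 1 alone the test passed in 48 of 54 genes, and in replicate 2 alone in 45 of 54. In 44 of the 54 the leading transcript was annotated.

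Alternative exons of synaptic, myelin and metabolic genes were measured from the transcript models too. These counts are not limited to full-length reads, since ISM reads count where they cover the exon. In Mbp, the 123 nt coding exon at chromosome 18, 82578936 to 82579058, was included in 12.3% (Wilson interval 11.8 to 12.9) of informative reads in replicate 1 and 15.1% (14.5 to 15.7) in replicate 2, and the 78 nt exon at 82561778 to 82561855 in 5.51% and 6.74%. Pkm used the exon at chromosome 9, 59675029 to 59675195, in 91.0% ± 0.078 of reads and that at 59675568 to 59675734 in 8.94% ± 0.066. Snap25 used the exon at chromosome 2, 136770057 to 136770174, in 92.0% ± 1.76 and that at 136769743 to 136769860 in 7.96% ± 1.71. The AMPA receptor genes also carried exon pairs of equal length, 115 nt. In Gria2 the exon at chromosome 3, 80691320 to 80691434, was in 68.4% ± 1.56 of reads and that at 80690404 to 80690518 in 31.5% ± 1.89. In Gria1 the exon at chromosome 11, 57309769 to 57309883, was in 71.1% ± 3.55 and that at 57310608 to 57310722 in 26.8% ± 3.02.

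Further exons had intermediate use. The 45 nt exon of Camk2b (chromosome 11, 5981070 to 5981114) was included in 79.0% (77.1 to 80.9) of reads in replicate 1 and 86.0% (84.1 to 87.7) in replicate 2, and the 39 nt exon of Ndrg4 (chromosome 8, 95712325 to 95712363) in 94.0% ± 0.103. Inclusion was 30.7% ± 1.18 for the Ndrg2 exon (chromosome 14, 51911086 to 51911127), 66.5% ± 0.030 for the calcineurin gene Ppp3ca (chromosome 3, 136932011 to 136932040) and 79.1% ± 4.25 for Aplp2 (chromosome 9, 31167561 to 31167728). Cadm1, a cell adhesion gene, had 3 such exons on chromosome 9, at 47818734 to 47818817 (28.1% ± 4.45), 47829377 to 47829409 (43.8% ± 1.10) and 47836717 to 47836770 (8.83% ± 0.958). For the first of them 2466 reads over both libraries were informative, while Cadm1 had 36 and 62 full-length reads in replicates 1 and 2. An unannotated 303 nt exon of the myelin gene Mobp (chromosome 9, 120168223 to 120168525) was included in 6.52% ± 0.487. Among the 60 isoform genes fixed by name, 99 exons in 39 genes lay between 5% and 95% inclusion, and 61 had a length that is a multiple of 3. Between the libraries 10 exons differed (Fisher's exact test, adjusted p under 0.05; 14 at an unadjusted p under 0.05), among them exons of Mbp, Snap25, Camk2b, Gria1, Cadm1, Aplp2 and Camk2g.

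**Figure D3:**
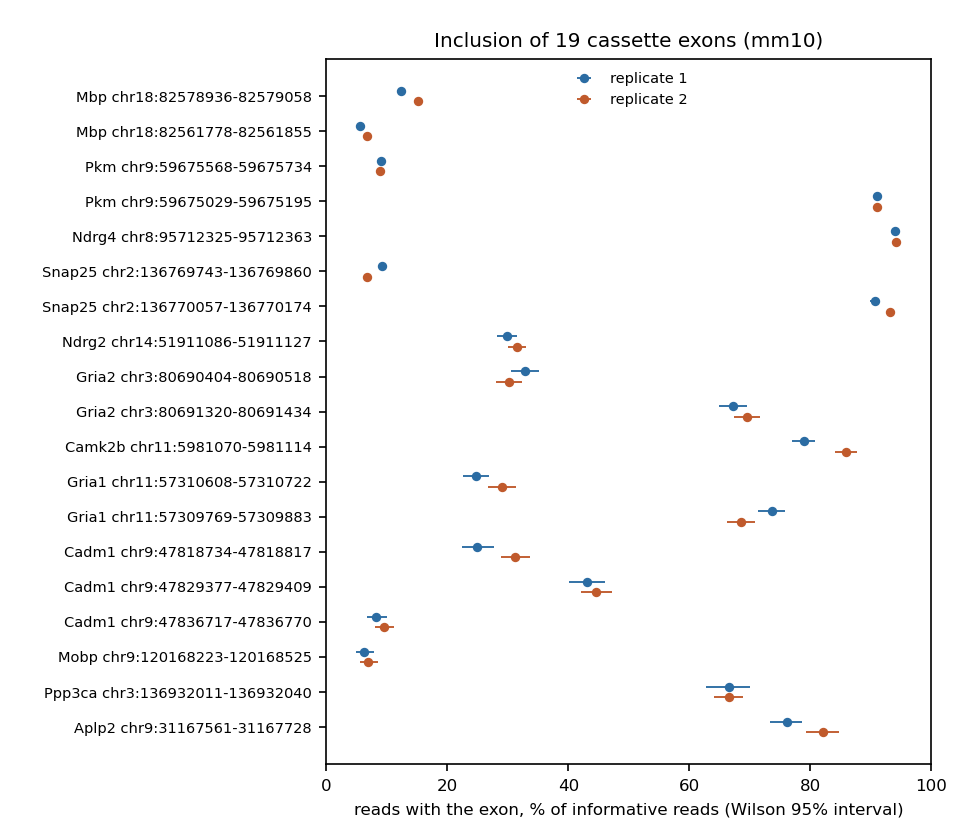
Inclusion of 19 of the 20 cassette exons with the most informative reads, as the percent of reads that carry the exon (horizontal axis), per library with its Wilson 95% interval; each line names the gene and the exon's mm10 position. The Pkm pair lies near 8.94% and 91.0%, and the Camk2b exon at 79.0% and 86.0%.

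Isoform use differed detectably between the libraries in few genes. Of the fixed isoform genes, Mbp-211 had 80.5% of reads in replicate 1 and 76.8% in replicate 2 (adjusted p 4.8e-09) and Ndrg4-202 80.1% and 75.7% (3.3e-08), by exact two-sided Fisher tests. Camk2b-209 had 66.2% and 73.5% and Snap25-201 89.2% and 91.3%. Over all genes, 101 of 6413 differed at an adjusted p under 0.05 (541 at an unadjusted p under 0.05), with the leading share higher in replicate 2 in 61. Part of this count is naming: of 65877 splice chains present in both libraries, 4573 (6.94%) had another class in the other file, and with each such chain counted alike in both, 70 genes differed, 68 of them among the 101. Atp2b1, a calcium pump gene, is such a case, with 75.3% and 0% as named and 74.5% and 80.3% when counted alike (adjusted p 0.258).

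Unannotated transcripts recurred between the libraries. Of the 21009 NIC and NNC splice chains with at least 2 reads in replicate 1, 14363 (68.4%, Wilson interval 67.7 to 69.0) had a read in replicate 2, and 13737 of 18094 (75.9%, 75.3 to 76.5) in the other direction. For Known transcripts of several exons, matched by identifier to Known ones only, the shares were 90.0% and 95.8%. The measures are unlike, since the NIC and NNC chains could match a chain of any class. Reads per transcript differ too. At 2 reads or more, replicate 1 had 1447563 reads over 19103 Known models and 151873 over 21009 NIC and NNC models. The shares depended on the read minimum, with 28.5% and 34.5% at 1 read and 95.3% and 97.5% at 5 reads. In 686 of 9270 genes with at least 20 full-length reads an unannotated transcript led in both libraries, with the same chain in 491. The 10 with the most reads were Apbb1, Hnrnpk, Ttc3, Oaz2, Dctn2, Oaz1, Rapgef4, Rpn2, Meg3 and Chmp1a. The antizyme genes Oaz1 (chromosome 10, 80826656 to 80829290) and Oaz2 (chromosome 9, 65676548 to 65690300), whose mRNAs are read through a programmed ribosomal frameshift, gave their leading NIC transcripts 95.3% and 96.9%, and 93.2% and 93.6%, of reads in replicates 1 and 2. How these leading transcripts differ from the annotated ones was not examined, so the class alone does not show a new splice form. The dynactin gene Dctn2 gave its NIC transcript 85.9% and 86.9%, Chmp1a its NNC transcript 89.5% and 91.2%, Rapgef4 its NNC transcript 55.1% and 51.7%, and the lincRNA gene Meg3 its NIC transcript 36.0% and 35.3%. Hnrnpk had 34.1% and 34.4%, Ttc3 19.6% and 25.8% and Rpn2 56.7% and 58.2%. Of the 9270 genes, 3872 (41.8%, Wilson interval 40.8 to 42.8) had a second transcript with at least 10% of reads.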

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

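The spike-in reads were counted without any test. Synthetic RNAs of the SIRV and ERCC sets, which enter none of the comparisons of mouse genes, took 711 reads in replicate 1 and 295 reads in replicate 2, both above the 3 reads that a count of 0 allows. That is 356 and 166 per 1000000 reads in mouse genes. The ERCC RNAs had 370 and 127 reads and the SIRV RNAs 341 and 168. The labels do not state how much was added to each sample, and no explanation of the difference was tested.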

How the results depend on the processing

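The 2-fold limit, the length and GC trends and the common class of splice chains were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the samples form only 1 group. Leaving out a replicate gives no value for the gene test, the isoform test between libraries and the list ratios, which need both, and 2 samples allow no other splits. The count of differing genes, 2872, ran from 2305 (length trend removed, 1875 shared) to 2970 (TMM, 2344 shared) and was 935 with the 2-fold limit. Lists outside the percentile range numbered 4 with TMM, 2 with known transcripts only (ribosomal proteins and Alzheimer-associated genes) and 2 with the length trend removed (meningeal fibroblasts and postsynaptic genes); the Alzheimer-associated and postsynaptic lists were inside the range otherwise. The Known share was 78.2% over transcripts with at least 2 reads. Genes with differing isoform use numbered 43 with known transcripts only (3937 genes tested), 263 with ISM transcripts (7403 tested), 92 at 50 reads and 70 with common classes; cassette exons numbered 52 with known transcripts only, of which 8 differed. Shared unannotated chains numbered 24278 (28.5%) and 24524 (34.5%), for replicate 1 and 2 taken first, at 1 read and 5809 (95.3%) and 5144 (97.5%) at 5 reads. The share of genes with a second transcript was 59.6% at a 5% threshold, 19.2% at 20%, 35.7% at 100 reads, 29.7% with known transcripts only and 47.8% with ISM transcripts. For these shifts, the cause was not tested. Leaving out each replicate gave 13735 to 13761 CPM for Hspa8, 3482 to 6428 CPM for Apoe, 427 to 1271 CPM for Camk2a, 72.7% to 74.3% Known reads, 45 to 48 genes with a leading transcript, 107 to 112 cassette exons and 39.9% to 41.3% of genes with a second transcript. Of the 115 genes taken as the most abundant overall or in a list, 24 had a level that moved by over 1.5 times when a replicate was left out. For the 20 genes with the largest ratios, 120 values under an alternative kept their direction and their call (genes under a read minimum gave none). This outcome was largely set by the choice of these genes. Scaling moved their log2 ratios by only 0.14, and other read minimums left them as they were. The trends could not be removed for genes without reads of a Known transcript. With known transcripts only, 9 of the 20 gave a value. At 2 reads the shares of all classes except Antisense, Known included, moved by more than the SD. Of 78 list values, 70 stayed on their side of the percentile range, 6 came inside it and 2 went outside it. A change of sign was seen in 10 of the 78, 0 of them in a list outside the range: CA3 cells, dentate granule cells and thalamus with TMM, dentate granule cells, interneurons, endothelial cells, ependymal cells and striatum with known transcripts only, and CA2 and dentate granule cells with the length trend removed. At this depth 42.3% of simulated 2-fold changes and 83.7% of 4-fold ones were called, with counting noise as the only spread.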

Other observations

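Apart from the sign test on held-out hypothalamus and midbrain genes, whose lists and criterion were written once the pattern had been noticed in other genes but before their own values were seen, the tests that weigh explanations here were chosen after the results were seen; the gene test and the list percentiles without a trend removed were planned for the fixed lists.

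Some unannotated loci opposite known genes had many reads. A locus opposite Map1b, which encodes a microtubule-associated protein (chromosome 13, 99422021 to 99424618, plus strand, mm10), had 1064 reads in replicate 1 and 1303 in replicate 2, and a locus opposite Tmem170b (chromosome 13, 41637330 to 41639197, minus strand) 492 and 962. Loci opposite Rab11fip4 (644 and 559 reads), the glutamate transporter gene Slc1a2 (661 and 533), Snhg11 (676 and 434) and AI593442 (439 and 488) followed. An intergenic locus at chromosome 4, 133096112 to 133101553, had 603 and 291 reads, and a locus at chromosome 17, 39843013 to 39845444, minus strand, opposite Gm26917 and Gm42418, had 727 and 116; it overlaps the annotated genes CT010467.1 and AY036118 on its own strand. Of 838 unannotated loci with at least 10 reads in replicate 1, 802 (95.7%) overlapped one on the same strand in replicate 2. How the strand of each read was set is not given in the sources used here, so antisense reads are uncertain.

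The vesicular glutamate transporter gene Slc17a7 and the postsynaptic gene Nrgn, chosen after their values were seen, stood at 26.4 ± 6.45 and 28.8 ± 7.38 CPM (SD, n = 2), far below Chn1 of the same list. Lists of other brain regions, added after the data were seen, had few reads in replicates 1 and 2: 24 and 5 over 6 cerebellum genes, 3 and 1 over 5 pituitary genes, and 0 and 0 over 8 hindbrain and spinal cord genes.

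Replicate 1 held transcripts of hypothalamus and midbrain that replicate 2 nearly lacked: 12 genes noticed in the data (among them Pmch, Hcrt, Avp, Oxt, Trh, Cartpt, Calcr, Slc6a3, Th, Chrna6 and Slc10a4) had 934 and 11 reads. Depth predicted 832 reads in replicate 2 and 1.32% of these were seen. With the length trend removed the upper quartile of the log2 ratios stayed at -3.54 (median -4.73). The 12 genes were picked for such ratios, so these values partly restate the choice. In the gene test, adjusted over all tested genes, all 12 departed from the depth share, and all 12 did with the length trend removed. For these 12 genes this argues against depth or the length trend alone. RNA from hypothalamus and ventral midbrain in replicate 1 is a candidate explanation. Of 19 other marker genes with at least 5 reads, 16 were higher in replicate 1 (one-sided exact sign test p 0.0022). These were 8 of 8 for hypothalamus and 8 of 11 for midbrain. Of all genes with as many reads 60.4% were higher in replicate 1, and 0.93% of 10000 random sets matched on expression had 16 or more. The sign test sets the genes against an even split, not against the 60.4%. It, the random sets and the permutation test below treat genes as independent, but markers of 1 tissue can move together. Their values therefore describe these 2 libraries only and measure no spread between samples. The most abundant of the 16 were Hap1 (165 and 53.3 CPM) and Resp18 (54.0 and 7.86 CPM). Aldh1a1 (173 and 180 CPM), Nr4a2 (58.0 and 112 CPM) and Tph2 went the other way. The midbrain list summed to 322 and 314 CPM. Aldh1a1 and Nr4a2 had 346 and 116 of its 644 reads in replicate 1 and 321 and 200 of its 560 in replicate 2. The sum therefore says little about its other genes. Among matched random lists hypothalamus lay at percentile 14.7, inside the range, and midbrain at 1.82. With known transcripts only these were 0.03 and 3.655. The median CPM of the hypothalamus list was 2.00 and 0, close to the floor, so its percentile decides little. Of the 19 genes, 10 had more than 3 reads in replicate 2 too, and 0 are in the fixed lists. Counted alike, 31 of 38 genes of the thalamus, cortical layer, striatum, ependymal, choroid plexus, meningeal and cerebellum lists had the higher CPM in replicate 1 too. The lists were unlike, with 7 of 7 meningeal, 6 of 7 choroid plexus, 6 of 7 striatum and 5 of 7 cortical layer genes, but 2 of 5 thalamus genes. The median log2 ratio of the 38 was -0.80 against -2.13 for the 19 (two-sided permutation p 0.0025). The direction is therefore not particular to hypothalamus and midbrain, and RNA of other neighbouring tissue stays open. Beyond these technical explanations the design, with 1 group, gives no biological one to test, and whether the dissection or the animals differed stays open.

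Many genes, 2872, differed between the libraries. Removing the trend on transcript length, which explained 13.1% of the variance of the ratios across genes with at least 100 reads, gave 2305 calls, 1875 of them among the 2872, and removing that on GC content (0.248%) gave 2876, with 2562 among them, so neither trend is the whole cause. Whether RNA from hypothalamus and midbrain in replicate 1 accounts for these calls cannot be told apart. Of the calls, 1113 (38.8%) were higher in replicate 2 by more than 0.18, the upper end of the bootstrap 95% interval of the median log2 ratio of 41 hippocampal subfield genes (0.03), but single subfield genes spread more widely, from -1.61 to 1.16 (2.5 to 97.5 percentile), so the bound of a median decides nothing. With 1 group, no biological explanation from the design was tested, and differences between animals or dissections stay open.

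Of 13 immediate early genes, 12 had the higher CPM in replicate 2 and 5 passed the test there. With the length trend removed their median log2 ratio was 0.56, above all 10000 matched lists by the median over genes, which argues against length selection; the ratio of list medians used for the lists elsewhere gives only percentile 89.6, or 93.8 with the trend removed. A lower share of hippocampal neurons in replicate 1 may contribute and cannot be told apart: the median of 34 excitatory, CA1 and dentate granule cell genes was 0.39 with the trend removed, and the difference from the immediate early genes had a two-sided permutation p of 0.394 (100000 permutations). What difference a comparison of 13 and 34 genes could detect was not measured, so it stays open. Apart from the share of neurons, no biological explanation was tested, since the labels give no difference in handling or activity between the samples.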
